A study of Homo sapiens with 6 samples.

How the data were processed

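Total RNA of A549 cells was amplified with a 3′ in vitro transcription kit, labelled with biotin and hybridized to 1-colour Affymetrix arrays, per the labels' protocols. The 6 arrays fall into 2 groups by their titles, 3 of cells with a control hairpin and 3 of cells with a hairpin against TIGD1. The deposited values are log2 signals per probe set and array, made by the authors with GCOS and RMA, per the submitters' processing notes. Their versions are not given in the sources used here. The log base was not stated and was read from the range of the values, so that fold changes rest on base 2. RMA corrects the background, makes the distributions of the arrays alike and summarises probes into probe sets. A shift common to most genes would thus be removed before deposit. Single probes and scan dates were not used here, so batches of scanning were not tested.

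Of 49395 probe sets, 102 were controls and were left out of the gene tests. The platform annotation gave exactly 1 gene symbol to 45336 of the others, several to 1275 and none that could be used to 2682. No symbol was taken from a probe set with several. Symbols were looked up by Entrez identifier in a current gene table, which changed 0 of them, and 128 probe sets kept the symbol of the annotation. Each gene was represented by its probe set with the highest mean over all 6 arrays, which gave 18265 genes, 11837 of them with several probe sets and 6428 with 1. This rule can hide a change seen only by a dimmer probe set. The text names disagreement between the probe sets of a gene for some genes only. Among others, log2 changes of opposite sign were found for MMP2 (-0.60 to 0.19), MUC5B (-0.10 to 0.79), HLA-B (-0.14 to 0.33) and VIL1 (-0.10 to 0.71).

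Genes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a trend, as 3 arrays against 3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Counts at 1.5-fold and 2-fold apply to genes past that threshold. Tables were prepared with Python 3.11.15 and pandas 2.3.3. A total of 40 gene lists were fixed before the data were examined, with 894 entries, of which 832 matched a tested gene. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 40 lists. They were tested again with the correlation estimated for each list and with fry. With an estimate, camera also uses the 4 residual degrees of freedom, which by itself raises p-values. Members past the threshold were counted over all genes and adjusted over the list alone. A camera test compares the list's genes with all others, so its direction can differ from that of the list's median or mean.

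The genes to be named were set by a rule before the data were examined. They are TIGD1, the 12 largest rises and 12 largest falls past the threshold with separate groups and a log2 signal of at least 6 in the higher group, and up to 4 members of each list with the largest changes past the threshold. Relatives of TIGD1, ACTB and GAPDH, and in a list with none past the threshold the member with the largest difference, could also be named. Members named outside this rule (CXCL5, TRAF1, SUSD6, MDM2, IFIT3, IFIT2, OASL, DUSP4, DUSP5, DUSP6, SPRY2 and SPRY4) were chosen after their values were seen.

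The gene and list tests were tested on simulated data with the real genes' means and spread. Of 50 genes changed at each size in the comparison of shTIGD1 with shControl over 18265 genes, 34% were recovered at 1.2-fold, 98% at 1.5-fold and 100% at 2-fold and 3-fold. Of 176 calls, 10 were false. When 1 list was shifted by 0.3 on the log2 scale, that list alone was called. Genes were simulated as independent, so list calls made through correlated genes were not tested. Among the other splits of the real arrays, the highest number of lists called was 3. The simulation changed 200 genes, while 4345 passed in the data, so the recovery at 1.2-fold need not carry over. No pair of arrays was a copy: at most 184 probe sets had equal values on any pair.

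Alternatives tried were the mean of a gene's probe sets, each probe set on its own, a repeated quantile normalization, equal array medians, filters on dim genes, eBayes with trend and robust settings, array weights, the replicate number as a block, limma's treat against 1.2-fold, and leaving out each array. After the data had been seen, the second brightest probe set and scaling on hybridization or poly-A controls were added. For the control scalings, which add 1 value to every gene of an array, counts, TIGD1 and lists are given, and of the named genes only how many turned. These scalings leave a list's difference from the other genes in mean log2 change as it is. A camera call that held under them is therefore no independent support. No transcript sequences were used, so sites for the hairpins in other transcripts were not analysed here.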

Results

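Gene expression was measured with a microarray in A549 cells, an established human line derived from a lung adenocarcinoma. The cells had received a lentivirus carrying a short hairpin RNA (shRNA), which directs the cell's small RNA machinery to a matching transcript. In one group the hairpin was directed at TIGD1 (target sequence CTGCTAACACAACATCCAT), a gene derived from a pogo-type transposase. In the other it carried a control sequence (TTCTCCGAACGTGTCACGT). Each group had 3 arrays, 6 in all, and their number limits the precision of every value below. The deposited values were log2 signals for 49395 probe sets per array, and the median signal of an array lay between 6.27 and 6.28. After 1 probe set had been taken per gene, 18265 genes were compared. The labels number the arrays of a group as replicates without saying that they came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

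The comparison asks which transcripts differ when TIGD1 is targeted. TIGD1 itself did not pass the test. Its single probe set read 6.96, 6.93 and 6.85 on the shControl arrays and 6.88, 6.84 and 6.86 on the shTIGD1 arrays. The means were 6.91 ± 0.06 and 6.86 ± 0.02 (SD, n = 3 each), a log2 difference of -0.06 with an SE of 0.04 (limma adjusted p = 0.389). The 95% interval of the difference ran from -0.16 to 0.04, which corresponds to a change between -10.3% and 3.15%. An exact permutation test, two-sided, gave p = 0.3, where 0.1 is the smallest value that 3 arrays against 3 can give. The TIGD1 signal lay at the 49.8th percentile of all genes, below the 95th percentile (7.77) and above the median (4.85) of 31 marker genes of immune and endothelial cells. Because the targeted transcript did not pass as lower, the groups are called "the arrays labelled shTIGD1" and "the arrays labelled shControl". Every direction below is that of the labels.

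Among the other genes, transcripts of inflammatory cytokines and of p53 targets were lower in the arrays labelled shTIGD1, and transcripts of endoplasmic reticulum chaperones were higher. As lists, the latter groups missed the threshold with an estimated correlation between genes (adjusted p = 0.0634 for p53 targets and adjusted p = 0.0586 for chaperones), while the NF-kB targets held (adjusted p = 0.0285). The cytokine genes CCL20, TNF and IL6 fell, by 1.08, 0.93 and 0.80 on the log2 scale (SE 0.04, 0.06 and 0.05; 3 arrays per group). The p53 targets FAS and CDKN1A fell by 1.08 and 0.63 (SE 0.05 and 0.04). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 0.43 (SE 0.04), and the epithelial adhesion genes EPCAM and CDH1 rose by 0.87 and 0.66 (SE 0.06 and 0.04). Epithelial markers as a list did not pass (median 0.00, camera adjusted p = 0.0949), with 20 of 24 members not past the threshold.

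In all, 4345 of 18265 genes (23.8%) passed a limma adjusted p of 0.05, 1789 higher and 2556 lower in the arrays labelled shTIGD1. Most of these differences were small, with a median absolute log2 change of 0.24. A change of at least 1.5-fold was reached by 202 of them (145 higher, 57 lower), and one of at least 2-fold by 29 (24 higher, 5 lower). The values of the groups did not overlap for 7732 genes (42.3%), where chance gives 10%. The split between higher and lower calls depended on the scaling. When arrays were levelled on the bioB, bioC and bioD hybridization controls, the median log2 change of all genes moved from -0.04 to 0.17, with 8738 genes higher and 361 lower. Levelling on the poly-A controls moved it to 0.30, with 13965 higher and 119 lower. Changes below are given as deposited, and falls smaller than 0.21 or 0.33 respectively turn into rises under these scalings.

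**Figure D1:**
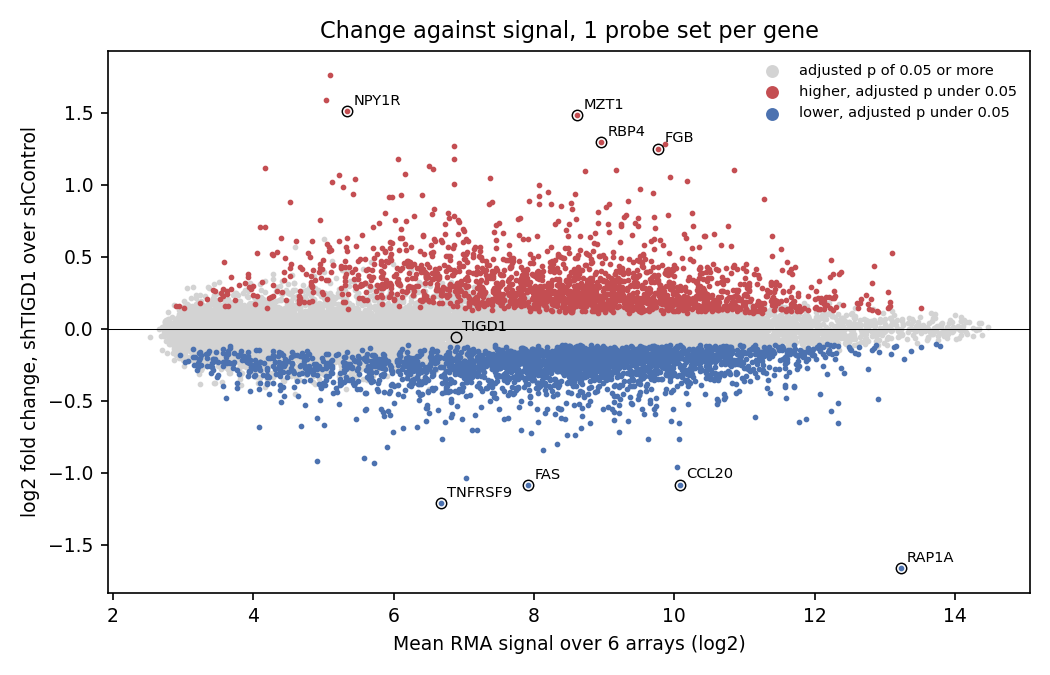
Each point is a gene, with its mean log2 signal over 6 arrays on the horizontal axis and its log2 fold change, shTIGD1 over shControl, on the vertical axis; red and blue points passed an adjusted p of 0.05. Circled genes are labelled: TIGD1 lies at -0.06, and the RAP1A point at -1.66 is a single probe set that the other RAP1A probe sets do not follow.

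The largest rises among genes with a signal of at least 6 in the higher group were in NPY1R, a neuropeptide Y receptor, and in MZT1, a component of microtubule-nucleating complexes. NPY1R went from 4.58 ± 0.05 to 6.09 ± 0.09 (at least 2.85-fold, adjusted p = 0.000128) and MZT1 from 7.87 ± 0.17 to 9.36 ± 0.05 (2.80-fold, adjusted p = 0.000318; SD, n = 3 each, limma). A mean under 5 lies near background, so the changes of NPY1R, BST2, MMP1, VIL1 and TIGD3, whose lower group had such a mean, are lower bounds. Several secreted plasma proteins followed. RBP4, the retinol carrier, rose 2.46-fold, FGB, the beta chain of fibrinogen, 2.38-fold, and the complement factor CFI 2.16-fold. The other genes of this group were IER3IP1 (2.43-fold), the interferon-inducible IFI27 (2.41-fold), ARSJ and FGFBP1 (2.27-fold each), FAM228B (2.19-fold), BTF3L4 (2.15-fold) and LXN (2.15-fold). In all 12, no probe set of the gene passed the test in the opposite direction. The highest adjusted p among them was 0.00232, for CFI.

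The largest fall of any single probe set taken for a gene was in the brightest of 4 probe sets assigned to the small GTPase RAP1A, from 14.06 ± 0.04 to 12.40 ± 0.03 (log2 change -1.66, SE 0.04, limma adjusted p = 4.76e-05, n = 3 each). The remaining RAP1A probe sets went the opposite way, with log2 changes of 0.30, 0.33 and 0.43 that all passed the test. No direction is therefore given for RAP1A. TNFRSF9, a receptor of activated lymphocytes that is also induced in other cells, fell 2.31-fold (adjusted p = 0.000695). FAS fell 2.12-fold (adjusted p = 0.000233) and the chemokine CCL20 also 2.12-fold (adjusted p = 0.000128). They were followed by the protease inhibitor PI3 (2.05-fold), the chemokine CXCL3 (1.95-fold), TNF (1.91-fold), CCL5 (1.87-fold), TRIML2 (1.79-fold), IL1A (1.76-fold), IL6 (1.74-fold) and TNFAIP3 (1.70-fold), a feedback inhibitor of NF-kB signalling.

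**Figure D2:**
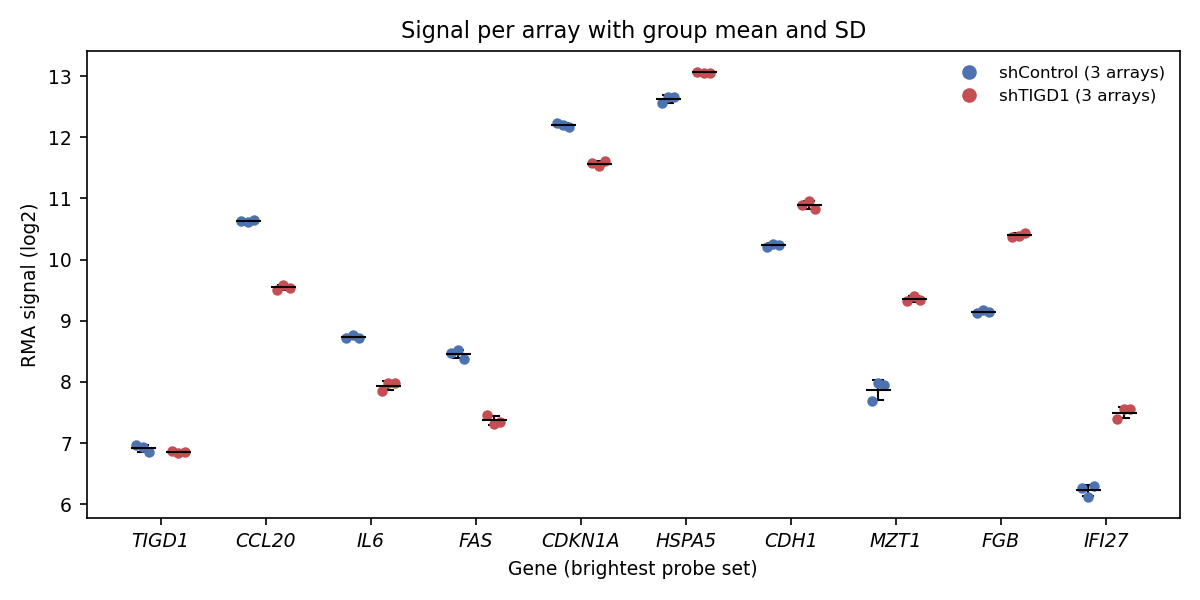
Log2 signal of 10 genes on the 3 shControl arrays (blue) and the 3 shTIGD1 arrays (red), with the group mean as a horizontal line and the SD as error bars. TIGD1 overlaps between the groups, while the arrays of the other genes shown lie apart.

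Of 40 gene lists fixed before the data were examined, 6 passed camera at an adjusted p of 0.05, 5 lower and 1 higher in the arrays labelled shTIGD1. With an estimated correlation between genes, 1 of them held, the NF-kB list. The estimates were -0.003 for the NF-kB, -0.028 for the chaperone, -0.030 for the mesenchymal and 0.003 for the MYC list. These lie under the preset 0.01, so the higher p-values of these lists do not come from correlated members. For the p53 (0.047) and ERK (0.068) lists the estimate was above it. By fry, which asks whether the members of a list move one way on balance, 29 lists passed, and 38 when either direction counted.

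NF-kB targets and inflammatory cytokines stood furthest from the other genes. Of 23 measured members, 21 fell and 0 rose, both over all genes and adjusted over the list alone, with a median log2 change of -0.57 (camera adjusted p = 7.24e-16, and adjusted p = 0.0285 with an estimated correlation). The median was -0.36 with hybridization and -0.24 with poly-A control scaling, and the camera call held under both. Here and for the lists below this adds no support, since the scalings shift the list and the other genes alike. CCL20, CXCL3, TNF and IL1A led the list, and the chemokine CXCL5 (-0.09, adjusted p = 0.273) and the adaptor TRAF1 (-0.14, adjusted p = 0.230) did not pass. Markers of immune cells had a median of -0.04, with 0 of 17 higher and 2 lower (0 and 1 adjusted over the list alone).

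The p53 target genes had a median of -0.35. Of 22 measured, 20 fell and 0 rose, again over all genes and adjusted over the list alone (camera adjusted p = 7.35e-12, but adjusted p = 0.0634 with an estimated correlation). FAS, a death receptor, was followed by BBC3, which encodes the pro-apoptotic protein PUMA (-0.74), the cell cycle inhibitor CDKN1A (-0.63) and SPATA18 (-0.63). SUSD6 (-0.08, adjusted p = 0.156) and MDM2 (-0.07, adjusted p = 0.296) did not pass with their brightest probe set. Of the 11 MDM2 probe sets, 7 passed as lower and 0 as higher, the lowest at -1.25. The median of the p53 list was -0.14 with hybridization and -0.02 with poly-A control scaling, and its camera call held under both. The related list of BCL2 family and death receptor genes did not pass (median -0.12, camera adjusted p = 0.274). It held 2 members that rose and 9 that fell, or 5 and 11 adjusted over the list alone, among them BAX (-0.33) and BIRC2 (0.23).

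Endoplasmic reticulum chaperones and genes of the unfolded protein response were higher. Of 21 measured, 12 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.15 (camera adjusted p = 4.55e-08, but adjusted p = 0.0586 with an estimated correlation). HSPA5 (0.43), the co-chaperone DNAJB9 (0.42), the transcription factor XBP1 (0.42) and HERPUD1 (0.39), which acts in degradation of misfolded proteins, had the largest rises. The median of the chaperone list was 0.36 with hybridization and 0.48 with poly-A control scaling, and its camera call held under both. The list of ATF4 targets and the integrated stress response did not pass (median -0.05, camera adjusted p = 0.395). There 1 member rose and 4 fell, also adjusted over the list alone, and CHAC1 (-0.62), STC2 (-0.56), SESN2 (-0.50) and DDIT4 (-0.46) were lower. Heat shock proteins had 1 rise and 3 falls on both counts (median -0.06, camera adjusted p = 0.875).

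MYC targets in ribosome biogenesis were lower, with 13 of 25 members falling and 0 rising (15 and 1 adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.00212, but adjusted p = 0.161 with an estimated correlation), and BOP1, NOP56, SRM and NOP2 fell by 0.32, 0.31, 0.30 and 0.30. This call ended with the second brightest probe set of each gene (adjusted p = 0.166). It also ended under the control scalings, where the median turned to 0.07 (adjusted p = 0.0735, hybridization controls) and 0.20 (adjusted p = 0.285, poly-A controls). Cytosolic ribosomal proteins had 0 of 27 members past the test in either direction, also adjusted over the list alone (median -0.02, camera adjusted p = 0.953); RPS15 had the largest difference, -0.08. Under hybridization control scaling that list passed as higher (median 0.19, adjusted p = 0.00506).

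Mesenchymal markers and factors of the epithelial to mesenchymal transition were lower as a list (median -0.10, camera adjusted p = 0.034, but adjusted p = 0.282 with an estimated correlation). Of 24 members 10 fell and 1 rose (11 and 1 adjusted over the list alone). SPARC, a matrix glycoprotein, fell by 0.70, the gelatinase gene MMP2 by 0.60, ACTA2 by 0.58 and the transcription factor ZEB1 by 0.36. The list of ERK pathway feedback genes was lower as well (median -0.13, camera adjusted p = 0.034, but adjusted p = 0.480 with an estimated correlation). It also holds EGFR and CCND1, which are not feedback genes in the strict sense. Its DUSP and SPRY members were mixed. DUSP5 (-0.35) and SPRY4 (-0.41) fell, SPRY2 (0.33) rose, and DUSP4 (-0.05) and DUSP6 (0.04) did not pass. Of 18, 9 fell and 2 rose (9 and 3 adjusted over the list alone), led by ETV4 (-0.54), the receptors EGFR (-0.52) and EPHA2 (-0.46) and the cyclin CCND1 (-0.44). Neither call held without shTIGD1 replicate 2 (adjusted p = 0.0572 for both), and the ERK call also ended without shControl replicate 2 (adjusted p = 0.131) and among genes with a signal of at least 5 (adjusted p = 0.0694). Both calls also ended with the mean of all probe sets of a gene (adjusted p = 0.193 for the mesenchymal and 0.123 for the ERK list) and with the second brightest probe set (adjusted p = 0.432 and 0.0661). Both medians turned positive under the control scalings, to 0.11 and 0.23 for the mesenchymal list and 0.08 and 0.20 for the ERK list. Their camera calls as lower than the other genes held there (adjusted p = 0.00273 and 0.000270 for the mesenchymal list, 7.38e-05 and 2.37e-06 for the ERK list). The lower p-values add no support, since the scalings leave a list's log2 difference from the other genes as it is. Epithelial markers did not pass (median 0.00, camera adjusted p = 0.0949). Of 24, 4 rose and 0 fell on both counts, and these were EPCAM, CDH1, the tight junction gene OCLN (0.54) and MUC1 (0.25).

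**Figure D3:**
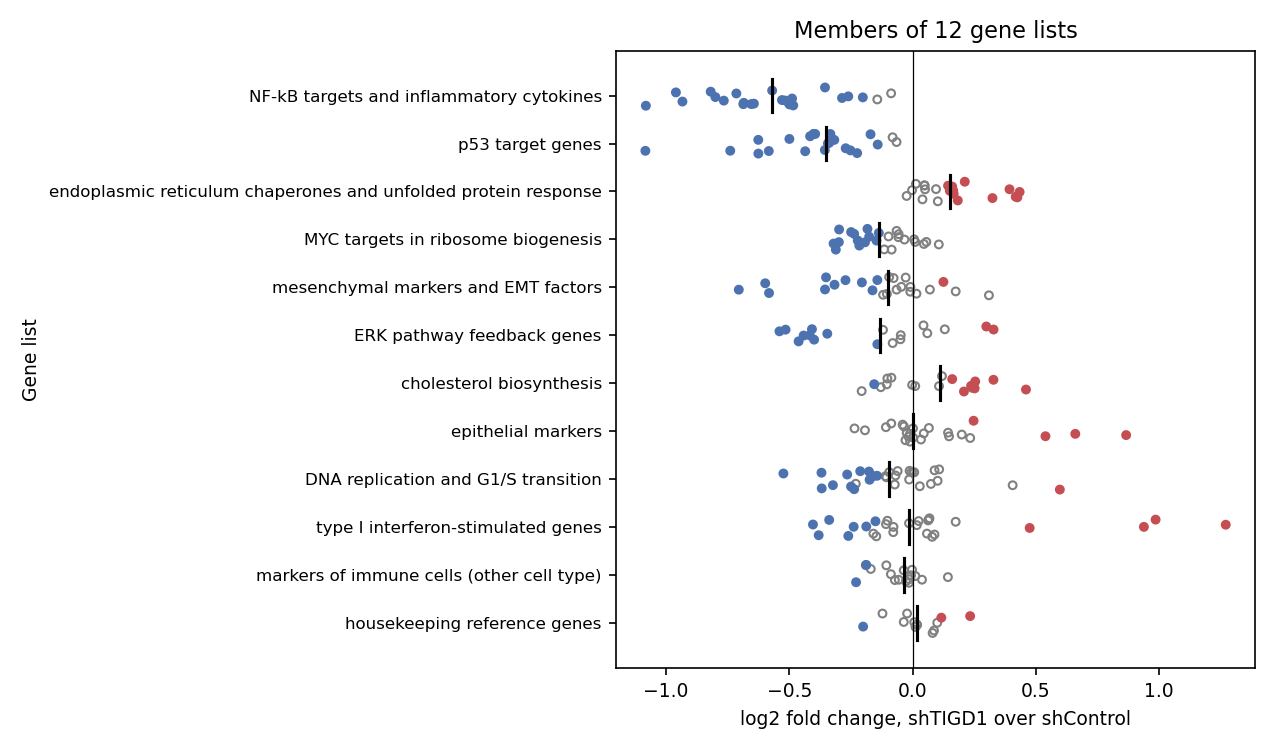
Log2 fold change, shTIGD1 over shControl (horizontal axis), of the measured members of 12 gene lists; filled points passed an adjusted p of 0.05, open points did not, and the black bar is the list's median. The NF-kB and p53 lists lie almost wholly to the left, with medians of -0.57 and -0.35.

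None of the remaining lists passed camera. In cell division, the DNA replication and G1/S list (median -0.09, adjusted p = 0.136) had 1 rise and 12 falls of 31, or 4 and 14 adjusted over the list alone. The helicase subunit gene MCM6 rose by 0.60 and the cyclin gene CCNE1 fell by 0.52. The G2/M and mitosis list had 4 of each on both counts (median 0.02, adjusted p = 0.340), including the transcription factor FOXM1 (-0.42). Genes of homologous recombination and the Fanconi pathway had 4 rises and 7 falls, or 5 and 9 adjusted over the list alone (median -0.12, adjusted p = 0.340), with RAD51AP1 at 0.50 and BLM at -0.45. Histone genes had 1 rise, H2AC6 (0.66), and 3 falls on both counts (median 0.00, adjusted p = 0.395). The senescence list held 4 rises and 5 falls, or 5 and 6 adjusted over the list alone (median -0.08, adjusted p = 0.806). In it IL6 and CDKN1A fell, while IGFBP3 (0.64) and the cell cycle inhibitor CDKN2A (0.56) rose. Another CDKN2A probe set rose by 3.42 from near background. A549 cells are known to have lost this gene by deletion, so its signal is weighed further below.

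Among signalling lists, the interferon-stimulated genes split. IFI27 (1.27), BST2 (at least 0.99), IFITM1 (0.94) and ISG20 (0.47) rose and 7 members fell on both counts, including IFIT3 (-0.40), IFIT2 (-0.38) and OASL (-0.34). The camera direction and the mean (0.06) were up and the median (-0.01) was down, with an adjusted p of 0.658. Antigen presentation genes had 7 rises and 2 falls, or 7 and 3 adjusted over the list alone (median 0.01, adjusted p = 0.136), with HLA-B at 0.33 and B2M at 0.23. Immediate early genes had 4 rises and 2 falls, or 6 and 4 adjusted over the list alone. JUN (0.44) and FOS (0.40) rose and IER3 (-0.40) fell, and the median (-0.01) and the mean (0.03) differed in sign (adjusted p = 0.395). The YAP and TAZ list had 7 rises and 5 falls on both counts, with a median of -0.01 and a mean of 0.03 (adjusted p = 0.340), and the receptor gene AXL rose by 0.39. TGF-beta targets had 2 rises and 3 falls on both counts. Their median (-0.03) and mean (-0.03) were below 0 while the camera direction was up (adjusted p = 0.953). Wnt targets had 0 rises and 3 falls on both counts (median -0.10, adjusted p = 0.360), with BMP4 at -0.32. The PI3K, AKT and mTOR list had 3 of each, or 4 and 3 adjusted over the list alone (median 0.01, mean -0.01, adjusted p = 0.634), with PIK3R3 at -0.49.

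In metabolism, 7 of 18 genes of cholesterol biosynthesis rose and 1 fell, or 8 and 4 adjusted over the list alone (median 0.11, adjusted p = 0.0728), with INSIG1 at 0.46 and SQLE at 0.33. That list passed with the mean of all probe sets (adjusted p = 0.0391), hybridization control scaling (adjusted p = 0.0497) and without shTIGD1 replicate 3 (adjusted p = 0.0406). Fatty acid and triglyceride synthesis had 4 of each on both counts (median 0.04, adjusted p = 0.225), and the elongase gene ELOVL6 rose by 0.83. Glycolysis had 4 rises and 3 falls, or 5 and 5 adjusted over the list alone, with ENO2 at 0.50 and GPI at -0.31 and with a median (-0.01) and mean (0.01) of opposite sign (adjusted p = 0.637). The hypoxia list had 3 rises and 1 fall, or 3 and 2 adjusted over the list alone (median 0.02, adjusted p = 0.340), led by INSIG2 (0.43). Oxidative phosphorylation had 5 rises and 2 falls of 30 on both counts (median 0.02, adjusted p = 0.227), with SDHD at 0.34, and passed with the second brightest probe set (adjusted p = 0.0410), hybridization (adjusted p = 0.00359) and poly-A control scaling (adjusted p = 0.00901). NRF2 targets had 4 of each, or 5 of each adjusted over the list alone (median 0.02, adjusted p = 0.339), with HMOX1 at -0.40 and UGDH at 0.38. Lysosome and autophagy genes had 3 rises and 7 falls, or 3 and 8 adjusted over the list alone (median -0.08, adjusted p = 0.316), with CTSZ at -0.43 and MAP1LC3B at 0.36.

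Matrix genes and matrix proteases had 5 rises and 7 falls on both counts (median -0.02, adjusted p = 0.806). The collagenase gene MMP1 rose by at least 1.12 (from 3.61 to 4.73) and PLAU fell by 0.48. Alveolar and lung epithelial markers had 2 of each, or 2 and 3 adjusted over the list alone (median -0.10, adjusted p = 0.420), with the mucin gene MUC5B at 0.78. The list of small RNA machinery had 0 rises and 4 falls, or 0 and 5 adjusted over the list alone (median -0.09, adjusted p = 0.225). In it XPO5 and EIF2AK2, which senses double-stranded RNA and is not part of that machinery, were both at -0.29. The relatives of TIGD1 had 1 rise, TIGD2 (0.30), and 1 fall, TIGD3 (-0.44), on both counts (median -0.03, adjusted p = 0.981).

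Markers of other cell types did not pass as lists. Fibroblast markers had 0 rises and 1 fall on both counts (median -0.03, adjusted p = 0.875), endothelial markers 1 of each, or 0 and 1 adjusted over the list alone (median -0.11, adjusted p = 0.339), and immune markers are given above (adjusted p = 0.634). Markers of squamous and other carcinoma lines had 1 rise and 1 fall, or 1 and 0 adjusted over the list alone (median -0.07, adjusted p = 0.693), and the rise was in VIL1 (at least 0.71). Long transcripts that are sensitive to RNA quality had 1 rise and 5 falls on both counts (median -0.10, adjusted p = 0.225). The log2 signal of the 3′ minus the 5′ control probe set was lower in shTIGD1 without overlap between the groups. It was 0.39 ± 0.02 in shControl against 0.34 ± 0.02 in shTIGD1 for ACTB and -0.07 ± 0.02 against -0.13 ± 0.02 for GAPDH (SD, n = 3 each). Housekeeping genes had 2 rises and 1 fall, or 3 and 1 adjusted over the list alone (median 0.02, adjusted p = 0.316). ACTB (0.10, adjusted p = 0.0582) and GAPDH (-0.02, adjusted p = 0.663) did not pass as deposited; the control scalings would add 0.21 or 0.33 to both. The signal of the bioB, bioC and bioD hybridization controls differed by -0.21 (shTIGD1 minus shControl) and that of the poly-A controls by -0.33, with no overlap between groups, but that of the cre hybridization controls by -0.04, with overlap. Background probes rich in G and C differed by -0.14 (6.42 ± 0.04 in shControl and 6.27 ± 0.04 in shTIGD1), also without overlap.

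Without shTIGD1 replicate 1 the number of genes past the threshold was 2742, and without shTIGD1 replicate 3 it was 2774, against 4345 with all arrays.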

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

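The tests of a signal trend, of immune cells and of all 3 explanations for genes near background were chosen only after the result was seen, as was the limit of 5 now set beside the one fixed beforehand for TIGD1. The criteria of the tests of immune cells and of a squamous line were also changed after their values were seen. Earlier criteria for the explanation by immune cells did not all give the same answer, so its result is to be read with caution.

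Among 3957 probe sets without exactly 1 gene symbol, which the gene comparison leaves out, 385 were higher and 385 lower in the arrays labelled shTIGD1 past an adjusted p of 0.05, and 32 were at least 1.5-fold higher. The beta-actin control probe sets were 0.0706 higher on the log2 scale (13.71 ± 0.01 against 13.78 ± 0.00, SD, n = 3 each), with no overlap between groups. That difference is relative to the deposited normalization.

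TIGD1 did not pass as lower in the arrays labelled shTIGD1. A swap of some arrays between the groups is argued against, since every array correlated better with its own group, with a smallest margin of 0.00162, but a complete exchange of the labels would leave that margin as it is. A TIGD1 signal near background cannot be told apart, since the floors disagree: the mean of 6.88 lies under the 95th percentile (7.77) of 31 marker genes of immune and endothelial cells, which met the criterion set beforehand, but above their median of 4.85 and the limit of 5 used for other genes, and TNF fell from 6.19 to 5.26. The array has 1 probe set for TIGD1, so a second one could not decide, and a knockdown that was weak or absent stays open, as does an effect of either hairpin on other transcripts.

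NF-kB and p53 targets were lower in the arrays labelled shTIGD1, with medians of -0.57 and -0.35 and 0 genes shared between the lists, though the p53 list missed the threshold with an estimated correlation (adjusted p = 0.0634). The choice of probe set is argued against, since over the second brightest probe sets the medians were -0.55 and -0.37. A trend with signal level is also argued against, since the lowest of 10000 random lists matched on mean signal had a median of -0.16 for the NF-kB list and -0.17 for the p53 list. Fewer immune cells as a cause are argued against by the markers at 5 or more in the controls, under a limit chosen afterwards. The median change of the 17 markers was -0.0359 (lower quartile -0.11). That of the 9 markers at 5 or more in the controls was -0.06 (lowest -0.23). Both lie above a limit of -0.28 derived from the NF-kB median. Only 1 of the 17 lies above 7.77, the floor set beforehand for TIGD1, but that floor was itself taken from immune and endothelial markers. The markers under 5 may be near background with little room to fall, so their changes cannot decide. Open and untested are an effect of lowering TIGD1, which these arrays do not show, and a difference between hairpins, viral doses or cultures, since each group has 1 hairpin. A difference in handling or scanning along the groups was not tested and stays open too. The poly-A (-0.33) and the bioB, bioC and bioD controls (-0.21) differed between the groups without overlap, the cre controls (-0.04) with overlap.

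A set of 14 genes with a control signal under 5 rose at least 2-fold in the arrays labelled shTIGD1 by at least 1 probe set, and 0 genes fell at least 2-fold to under 5. Their folds are lower bounds, since background holds up the control signal, and do not rank them: CDKN2A, which A549 cells are known to have lost by deletion, went from 3.93 ± 0.15 to 7.35 ± 0.12 by the most responsive of its 3 probe sets (at least 10.7-fold, SD, n = 3 each; log2 rises of 0.56 and 0.59 by the others), ANO1 rose at least 6.06-fold (1.36-fold and 1.01-fold by its others, the last not past the threshold), and ZBED2, BST2, COL13A1 and LY6K at least 3.39-fold, 3.08-fold, 3.05-fold and 3.01-fold; all were chosen after their values were seen. Faulty single probe sets are argued against for the direction of most of these genes but not for its size, since of 12 with several probe sets 10 had a second one past the threshold in the same direction, 8 at 1.5-fold or more and 3 at 2-fold or more, and 0 had one against it. RNA of a squamous line is argued against, since 0 of 6 measured squamous markers rose at least 2-fold (highest log2 change 0.0089). For liver, breast, prostate and intestinal lines 10 markers are too few. VIL1 among them rose by at least 0.71, but 1 of its 3 probe sets passed and both group means (3.81 and 4.52) lie near background. RNA of another line may account for the 14 rises against 0 falls, but genes switched on in the cells would give the same count; a deleted gene cannot be switched on, so CDKN2A goes against the latter for itself if the deletion, not measured here, holds and its probe sets read no other transcript.

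With all arrays 4345 genes passed the threshold, 202 of them at least 1.5-fold, and 6 lists. Among the 10 splits of the 6 arrays into groups of 3, only 1, the real split, gave as many genes, as many at 1.5-fold or as many lists, and the highest of the other splits gave 0 genes, 0 at 1.5-fold and 3 lists. With 10 splits a share under 0.05 cannot be reached.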

How the results depend on the processing

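The second brightest probe set and the control scalings were chosen after seeing the data. Genes past the threshold numbered 4345 of 18265 as deposited (23.8%). They were 10867 of 49293 with each probe set on its own (22.0%; 688 at least 1.5-fold, against 202), 2780 of 11837 with the second brightest probe set (23.5%), 9099 with hybridization control scaling (507 at 1.5-fold) and 14084 with poly-A control scaling (1076 at 1.5-fold). Leaving out 1 array gave 2742 to 3389. Asking for at least 1.5-fold left 202, for 2-fold 29, and treat against 1.2-fold 262. Keeping genes at or above the median signal left 125 at 1.5-fold, from fewer genes tested, and no value for TIGD1, which lies below it. The share of higher calls was 41.2% as deposited, 55.9% with the second brightest probe set and 52.0% over all probe sets. Lists past the threshold were 6, but 1 with an estimated correlation and 29 by fry. TIGD1 stayed between -0.09 and -0.03 without 1 array (highest adjusted p = 0.687), but was 0.15 with hybridization control scaling (adjusted p = 0.0388) and 0.28 with poly-A control scaling (adjusted p = 0.00227), which add 1 value to every gene. By that shift the sign of 12 and 39 of 153 called named genes changed, 0 and 8 of them past the threshold in the new direction. Cytosolic ribosomal proteins became 0.19 with hybridization control scaling. The cause was not tested.

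The replicate numbers did not pair the arrays: deviations of arrays with the same number correlated at -0.03, -0.13 and -0.09. With the replicate block 2388 genes passed, 2326 of them among the 4345, and the mesenchymal and ERK lists did not.

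Of 2325 values of named genes under these alternatives, other than the control scalings, 2096 kept direction and side of the threshold, 214 lost the threshold, 5 gained it and 10 turned. With the second brightest probe set RAP1A became 0.30, MAD2L1 -0.0305, DNAJA1 0.0536, HMGCS1 -0.0154, BNIP3 -0.0328, NDUFS3 0.0724, LAMP3 -0.0379, ESAM -0.0873 and MMRN1 0.0324; DNAJA1 was 0.0029 with the mean of its probe sets. Of these, RAP1A alone passed the threshold in the new direction. Named genes that lost the threshold numbered 31 with the replicate block, 26 with the second brightest probe set, 19 with the mean of all probe sets and 17 to 26 without 1 array. Of 713 list values, control scalings included, 685 stayed on their side of the camera threshold, 18 lost the call and 9 gained one (cholesterol and oxidative phosphorylation 3 each, immediate early genes, small RNA machinery and epithelial markers 1 each). The ribosomal list above, not called as deposited, was called in the other camera direction. Dim genes have the least room to fall, since a signal near background cannot go lower.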

Other observations

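The groups of plasma proteins, N-glycan genes and RAP1 regulators were chosen for testing after single genes had been seen, with those genes left out. Their camera p-values were adjusted over these groups alone, a milder correction than that over the lists fixed beforehand.

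SERP1, which stabilises proteins at the translocation pore of the endoplasmic reticulum, was higher by all 5 of its probe sets in the arrays labelled shTIGD1. The log2 changes ran from 0.33 for the brightest probe set to 2.23, the latter from 8.14 ± 0.09 to 10.37 ± 0.03 (SD, n = 3 each). The gene was chosen after its values were seen.

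FGB, RBP4, CFI and IGFBP1 are secreted plasma proteins made mainly by liver. A rise of such proteins as a group was a hypothesis tested on 36 others. They passed camera as higher only under that milder correction (adjusted p = 0.0338), and not with an estimated correlation (adjusted p = 0.349). Of these genes 8 rose and 4 fell, with a median of 0.04. Their unadjusted camera p was 0.0225. Among the lists fixed beforehand, cholesterol biosynthesis had a lower unadjusted camera p (0.0127) and did not pass (adjusted p = 0.0728). The fibrinogen chains FGG (0.79) and FGA (0.51), the clotting factor F7 (0.74) and CP (0.67) rose, while APOC1 (-0.49) and SERPINA3 (-0.32) fell. FGG and FGA belong to the same protein as FGB. Leaving FGB out thus does not make the test independent of the genes that prompted it. Genes of N-glycan assembly and transfer, tested because ALG5 was higher, also passed (28 genes, 9 rising and 2 falling, median 0.07, adjusted p = 0.00142, but adjusted p = 0.156 with an estimated correlation). ALG6 (0.26), ALG2 (0.24) and RPN1 (0.23) rose and ALG3 (-0.23) fell.

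The bright RAP1A probe set that fell was compared with the other 3. The test had been set to find them within 0.3 of no change if that probe set were at fault, or falling by more than 0.83 if the gene fell. The lowest of them was at 0.30 and the highest at 0.43, all higher and past the threshold, so that neither outcome was met. The rises go against a fall of the gene as a whole, and whether the bright probe set is at fault or reads another transcript stays open. Regulators and effectors of RAP1 gave a negative result as a group (24 genes, 5 rising and 2 falling, adjusted p = 0.437).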
